A study of Mus musculus with 4 samples.

How the data were processed

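Total RNA from the left ventricle of male C57BL/6 mice was measured on 4 single-channel arrays, 1 for each of 4 groups. The groups were wild-type (WT) and STIM1-deficient (STIM1KO) mice, each after a sham operation or after transverse aortic constriction (TAC). TAC narrows the aorta with a ligature and loads the left ventricle with pressure. Per the labels, surgery was done at 10 weeks of age around a wire of 0.3 mm, and tissue was taken 4 weeks later, at 14 weeks. Each array was assigned to its group from its title. The labels give an average heart weight to body weight value per group, which implies several mice, and do not say whether the RNA on an array came from 1 mouse or from a pool.

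The authors deposited 1 linear intensity per probe and array. Per the labels' protocols, RNA was amplified with amino allyl nucleotides and labelled with Cy5. The scanner, the background correction and the rule behind empty cells are not given in the sources used here. In the deposited intensity values, each array had been scaled to a median of about 20 over its own probes with a value. No value was 0 or negative, and dim probes were often left empty. The table held 23473 probes, of which 19607 had a value on all 4 arrays, 3464 on some and 402 on none. A gene symbol was paired with 16631 probes, none had several symbols, and 6842 were without a symbol here and were not named. Of these symbols, 3947 were updated through synonyms in a mouse gene table of assembly GRCm38.p6, which was used for names only, and 16569 then matched a current symbol. They stood for 16390 genes, of which 14039 had a value on all 4 arrays.

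Values were taken to log2. By a rule set before the data were examined, values as deposited would have been used if the array medians over the shared probes lay within 0.1 on the log2 scale. They spread over 0.101, so quantile normalization between arrays was used. For a gene with several probes, the probe with the highest mean over the 4 arrays stood for it. Genes were kept when they had a value on all 4 arrays and a mean log2 intensity at or above the median of such means, 4.87 (an intensity of 29.3), which left 7020 genes. No named probe with an empty cell came near this level, since the highest mean log2 intensity among 2406 such probes was 3.48.

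With 1 array per group no test, standard deviation between animals or p-value was computed, and the number of arrays limits the precision. Each comparison is a difference of log2 intensities, with the number of genes at or above 2-fold in each direction. The comparisons were TAC against sham in each genotype, STIM1KO against WT after each operation, and the response to TAC in STIM1KO minus that in WT, called the difference of responses. For 35 gene lists fixed before the data were examined, covering cardiac, metabolic, stress and signalling genes and markers of other cell types, the median log2 difference of the members passing the filter was placed among 10000 random lists of equal size matched on mean expression in 20 bins. A list was called apart at or below the 2.5th or at or above the 97.5th percentile, which happens for 1 in 20 random lists of unrelated genes. Where the genes of a list vary together, that rate can be higher. Lists with fewer than 5 members passing the filter were given no percentile, which left 30 lists. This percentile describes these arrays and is no test of the conditions.

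Genes named in the text were chosen by a rule written before the data were examined. Stim1 and the store-operated calcium entry list come first. In each response to TAC, the 10 genes with the largest differences each way among those at 2-fold followed, and in the other comparisons the 8 largest, leaving out clone and gene model names. Up to 4 members of each list described, and 10 fixed markers (Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Col1a1, Col3a1, Postn and Rcan1), were added. The text prints part of those the rule takes. Adhfe1, as 1 of 4 genes shared by both genotype comparisons, and Myl1, in the closing section, fall outside the rule and were chosen after their values were seen.

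Alternatives fixed beforehand were centring each array on its median, values as deposited, no filter on dim genes, a filter at the 75th percentile, an offset of 5.49 intensity units before log2 (the 25th percentile of all values), the mean over probes of a gene, and thresholds of 1.5-fold and 3-fold. Median centring and values as deposited differ only by a constant per array. A list's percentile is therefore the same under both by construction, and for percentiles they count as 1 check. The steps were tested on simulated data for the comparison of WT TAC with WT sham, with 7020 genes, 200 of them changed and noise with an SD of 0.2 per array. Of the changed genes, 5% at a true fold of 1.5, 46.5% at a true fold of 2 and 95.5% at a true fold of 3 came out at or above 2-fold, with 2, 9 and 3 unchanged genes beside them. Of 100 simulated lists of 20 genes, 4 stood apart without a shift and 99 with a log2 shift of 0.3. The simulated noise was independent between genes, so this does not cover lists whose genes vary together. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.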

Results

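The series addressed how the left ventricle of mice labelled STIM1KO differs from wild type under pressure overload. STIM1 is the calcium sensor of the endoplasmic reticulum that opens Orai channels in the plasma membrane. The 4 arrays, 1 for each genotype and operation, were single, so there are no replicates, and every difference below compares arrays rather than conditions. The labels give average heart weight to body weight values, with no unit, of 4.1 in WT sham, 6.7 in WT TAC, 4.5 in STIM1KO sham and 4.9 in STIM1KO TAC. Of 23473 probes, 21437 had a value on the WT sham array, 21605 on WT TAC, 21115 on STIM1KO sham and 21782 on STIM1KO TAC. The highest intensities were between 62746 and 70859.

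Among the 7020 genes passing the filter, the WT sham and WT TAC arrays had a Pearson correlation of 0.990, and the SD of the log2 differences across genes was 0.25. The STIM1KO sham array correlated at 0.987 with WT sham and 0.989 with WT TAC. The STIM1KO TAC array stood farther off, at 0.963 with WT sham and 0.974 with each of the others, with an SD across genes of 0.42 against STIM1KO sham. These correlations are across genes, which are not independent replicates. For 53 genes with 2 probes above the filter level, the log2 differences of the 2 probes correlated weakly, at r = 0.19 in the WT response (bootstrap 95% interval -0.19 to 0.48) and 0.08 in the STIM1KO response (-0.22 to 0.36). It was 0.19 between the sham arrays, 0.22 between the TAC arrays and 0.26 in the difference of responses. The error SD of a single probe estimated from these pairs was 0.26 in the WT response and 0.42 in the STIM1KO response. This is about the SD across all filtered genes in each, 0.25 and 0.42. In each of the 5 comparisons, 1 or 2 of these genes had a probe at 2-fold, and 0 had both. A difference given below for 1 probe is therefore open to error of that probe.

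Stim1 was lower on both STIM1KO arrays. Its quantile-normalized log2 difference was -1.004 between STIM1KO sham and WT sham (2.01-fold lower) and -1.30 between STIM1KO TAC and WT TAC (2.46-fold lower). These differences lay at percentiles 0.6 and 0.2 among the 500 genes nearest in level. The probe was below the filter level, with -0.84 in the sham arrays once an offset was added. Its normalized intensities were 41.6 in WT sham, 33.9 in WT TAC, 20.7 in STIM1KO sham and 13.8 in STIM1KO TAC. The probe thus shows a lower signal, not an absent one, and does not show whether the loss of STIM1 was complete. Whether the probe lies in the altered part of the gene is not given in the sources used here, so it checks the genotype labels only in part. Between TAC and sham, the Stim1 difference was -0.30 in WT and -0.59 in STIM1KO.

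Of 18 genes in the store-operated calcium entry list, 14 had a value on all 4 arrays and 7 passed the filter. None of these 7 reached 2-fold in any comparison, and the list of these 7 was not apart in any. With no filter on dim genes, the list between the 2 TAC arrays went from a median of -0.03 at percentile 39.1 to -0.32 at percentile 1.28, which is apart. Cracr2a, a cytosolic regulator of Orai channels, was higher by 0.76 in the WT response to TAC, 0.66 in the STIM1KO response and 0.70 in STIM1KO sham against WT sham. Orai1, the pore subunit, differed by 0.32 in the WT response and 0.11 in the STIM1KO response. In the difference of responses all 7 were below 0, with a median of -0.21 at percentile 13.3.

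**Figure D1:**
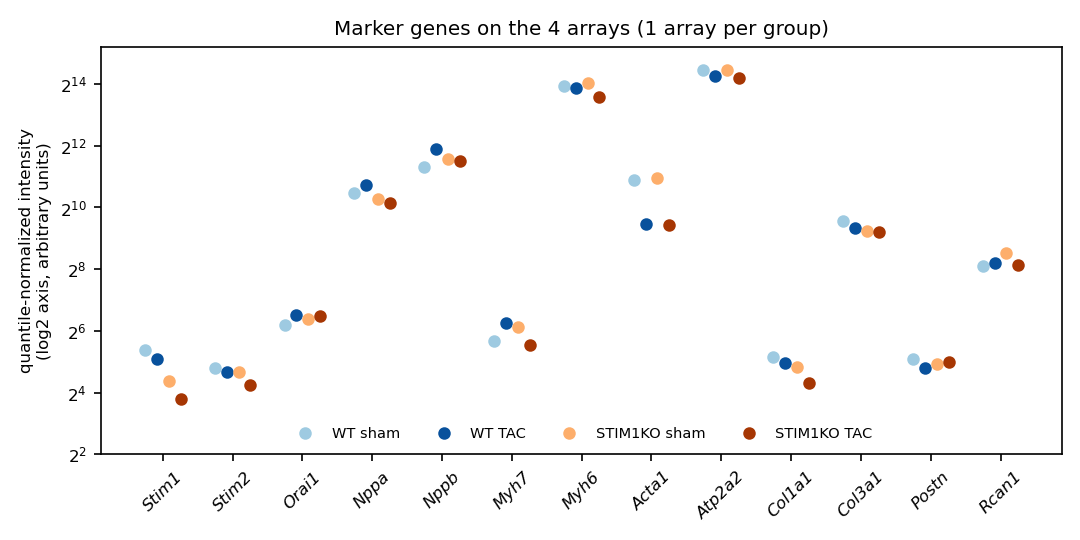
Quantile-normalized intensity (log2 axis, arbitrary units) of marker genes on the 4 arrays, 1 point per array and gene. Acta1 lies lower on both TAC arrays than on both sham arrays, with log2 differences of -1.41 and -1.52, and Stim1 lies lower on both STIM1KO arrays than on both WT arrays.

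The first comparison asked how the WT ventricle responded to TAC. Markers of hypertrophy were modestly higher on the TAC array. The log2 difference was 0.59 for Myh7, the slow myosin heavy chain of the fetal heart, 0.58 for Nppb and 0.24 for Nppa, which encode natriuretic peptides. In the other direction, Acta1, skeletal muscle alpha-actin, was 2.67-fold lower at -1.41. Of the 17 hypertrophy and fetal genes passing the filter, 12 were above 0 and 5 below, with a median of 0.13 at percentile 98.2 of matched random lists. The list was no longer apart with median centring, with deposited values or with the 75th percentile filter, at percentiles of 95.2, 95.2 and 92.6.

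Extracellular matrix genes were lower on the WT TAC array. Of 35 members passing the filter, 25 were below 0, the median was -0.14 and the percentile 0.38, and none reached 2-fold. Thbs2, a matricellular thrombospondin, differed by -0.60, Col12a1 by -0.49, Col8a2 by -0.43 and Col5a2 by -0.41. The fixed matrix markers Col1a1, Col3a1 and Postn, which encodes periostin, differed by -0.19, -0.22 and -0.26. Fibroblast markers had a median of -0.01 in the same comparison, at percentile 61.2, which was 0.03 with the values as deposited. Of 16 immediate early and heat shock genes, 9 were above 0, with a median of 0.15 at percentile 98.9. Ier3 was higher by 0.78, Jun by 0.53 and Egr1 by 0.49, and Klf6 differed by -0.63. This median was -0.034 with the 75th percentile filter.

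At 2-fold, 8 genes were higher and 14 lower in WT TAC. The 8 were Art3 (1.64), Sod1 (1.38), the cytosolic superoxide dismutase, Svil (1.28), Clstn2 (1.12), Myot (1.07), which encodes the Z-disc protein myotilin, Pon2 (1.07), Cyp2d12 (1.01) and Sctr, which was just at the threshold. Among the 14, Utp4 (-2.62), a factor of ribosome assembly, Ttc13 (-1.92), Fez2 (-1.62), Plac9 (-1.61), Mfsd6 (-1.56) and Golph3 (-1.43) were the lowest. A second, dimmer Mfsd6 probe differed by 0.17. Cacna2d1, an auxiliary subunit of voltage-gated calcium channels, differed by -1.28. The remaining fixed markers differed little, with -0.08 for Myh6, -0.20 for Atp2a2, the calcium pump of the sarcoplasmic reticulum, and 0.07 for the calcineurin regulator Rcan1.

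The same question in STIM1KO gave a wider spread of differences. Here Myh7 differed by -0.59, Nppa by -0.14 and Nppb by -0.06, and Acta1 was 2.87-fold lower at -1.52. Myh6, the adult myosin heavy chain, differed by -0.46 and Rcan1 by -0.40. The hypertrophy and fetal list was not apart, with a median of -0.01 at percentile 46.7, and 0.09 with the values as deposited. Among the collagens, Col1a1 differed by -0.53 and Col3a1 by -0.04, and Postn by 0.06. The matrix list had a median of 0.12 at percentile 92.2.

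Macrophage and monocyte markers were higher on the STIM1KO TAC array than on STIM1KO sham, with 11 of 17 above 0 and a median of 0.28 at percentile 99.6, or 0.17 at percentile 99.2 with median centring. Ctss, the lysosomal protease cathepsin S, was higher by 0.79, Folr2 by 0.66, the Fc receptor Fcgr3 by 0.62 and the complement component C1qc by 0.56. The STIM1KO sham array was itself low in these markers, with a median of -0.21 against WT sham at percentile 0.52. Between the 2 TAC arrays the median was 0.06 at percentile 66.97, and -0.06 with median centring and -0.055 with the values as deposited. The list of calcium handling in the sarcoplasmic reticulum also holds plasma membrane genes, such as Cacna2d1 and Atp2b1. It was lower on STIM1KO TAC than on STIM1KO sham, with 8 of 13 genes below 0. The median was -0.28 at percentile 2.31, or 3.28 with the 75th percentile filter. Cacna2d1 differed by -1.10, Trdn by -0.49, Atp2b1 by -0.49 and Atp2a2 by -0.28, and Itpr3 was higher by 0.50.

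At 2-fold, 88 genes were higher and 42 lower in STIM1KO TAC than in STIM1KO sham. The split was 99 and 33 with the values as deposited, and 70 and 56 with median centring. Myot (2.46), Vegfb (2.36), a member of the vascular endothelial growth factor family, Chac1 (2.28), a target of the unfolded protein response, Nptn (2.24) and Rpp25l (1.99) were the highest. Of these, all but Myot had their lowest value of the 4 arrays on STIM1KO sham. For example, Chac1 was at 17.8 there and 38.7 on WT sham, and Nptn at 78.1 and 146. The same held for Fbxo3, Arhgef3, Tmem115, Rhoc and Mlf2, the next in rank. Camk2n1, an inhibitor of the kinase CaMKII, was the lowest, with a normalized intensity of 111 on STIM1KO sham and 2.31 on STIM1KO TAC. The latter lies under the first quartile of that array, 5.38, so the size of the difference is not fixed by these data. With the offset before log2 it was -3.90. Crhr2 (-1.48), the imprinted RNA H19 (-1.42), Utp4 (-1.40), St3gal4 (-1.35), Ric3 (-1.30) and Tnfrsf12a (-1.30) followed Acta1.

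The WT and STIM1KO responses share no array, and across the 7020 genes they correlated at r = 0.27 (Spearman 0.29). Genes at 2-fold in both were Art3, Clstn2 and Myot among the higher ones and Acta1, Cacna2d1 and Utp4 among the lower ones. These are 3 each, against 0.10 and 0.084 expected for independent lists if every gene is equally likely to reach 2-fold. Probes prone to large errors would also raise the overlap, so it does not by itself show a shared response. With the offset before log2, Clstn2 (0.90) and Myot (0.99) were under 2-fold in the WT response and Cacna2d1 (-0.90) in the STIM1KO response. Cacna2d1 was also under it there, at -0.99, with the values as deposited. The 8 genes higher in WT had a median of 0.67 in STIM1KO, while the 88 higher in STIM1KO had a median of 0.09 in WT. The 14 lower in WT had a median of 0.23 in STIM1KO, and the 42 lower in STIM1KO had a median of -0.23 in WT.

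**Figure D2:**
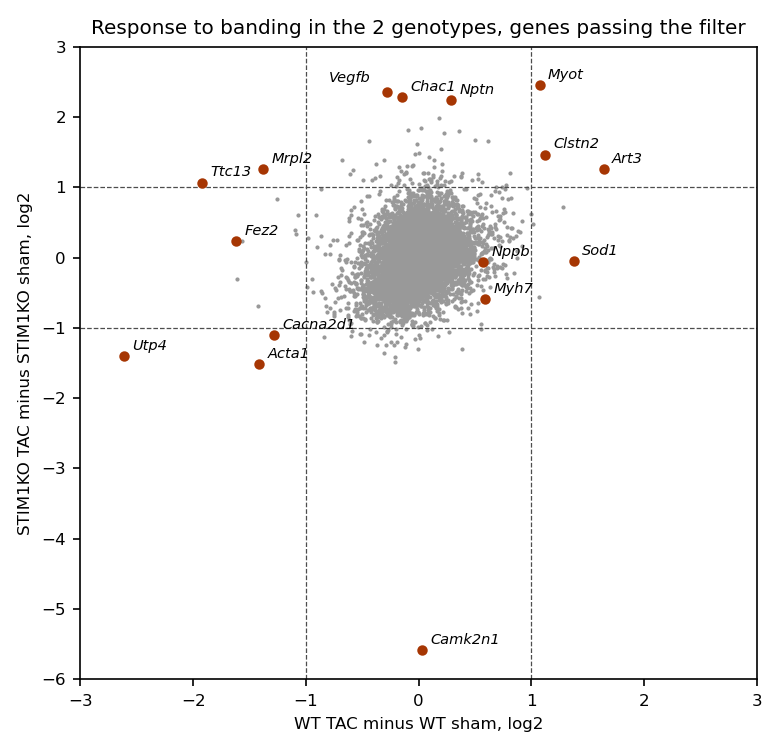
Log2 difference between TAC and sham in WT (horizontal axis) and STIM1KO (vertical axis), 1 point per gene for the 7020 genes passing the filter, with dashed lines at 2-fold and some genes named. The 2 responses correlated at r = 0.27, and Camk2n1 lies lowest in STIM1KO, at a position that rests on a dim value of 2.31 on the STIM1KO TAC array.

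The third comparison set STIM1KO against WT after the sham operation. Endothelial markers were lower in STIM1KO sham, with 15 of 16 below 0, a median of -0.28 and a percentile of 0.0. Flt1, a receptor of vascular endothelial growth factor, differed by -1.01, Tie1 by -0.67, Gpihbp1 by -0.61 and Sox17 by -0.55. Macrophage and monocyte markers were lower too, with 15 of 17 below 0 and a median of -0.21 at percentile 0.52, including Fcgr3 (-0.56) and Ly86 (-0.47). Fibroblast markers had a median of -0.18 at percentile 0.79, with 10 of 17 below 0, and Cygb differed by -0.53.

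The matrix list moved with these markers of other cell types. Of its 35 genes, 22 were below 0, and the median of -0.17 lay at percentile 0.1, or 5.45 with no filter on dim genes. Sparc, a matricellular protein, differed by -1.03, Col4a2 by -0.66, Col15a1 by -0.65 and Col1a2 by -0.63, while a second, dimmer Col15a1 probe differed by -0.012. This comparison and the WT response share the WT sham array. Col1a1 differed by -0.32, Col3a1 by -0.29 and Postn by -0.15. The other fixed markers differed by 0.47 for Myh7, 0.42 for Rcan1, 0.26 for Nppb, 0.09 for Myh6, 0.07 for Acta1 and -0.19 for Nppa. Atp2a2 differed by 0.02, which turned to -0.055 with the values as deposited.

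At 2-fold, 2 genes were higher and 37 lower in STIM1KO sham. Cpxm2 (1.28) and Gnb3 (1.17) were higher. Vegfb (-2.94), Xlr3b (-2.27), the mitochondrial ribosomal protein gene Mrpl2 (-2.12), Rpp25l (-2.04), Arhgef3 (-1.98), Rhoc (-1.91) and Riok3 (-1.71) were among the lowest.

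The fourth comparison set STIM1KO against WT after TAC. Immediate early and heat shock genes were lower in STIM1KO TAC, with 11 of 16 below 0 and a median of -0.39 at percentile 0.07. Klf2 differed by -0.97, Ier3 by -0.90 and Jun by -0.85, and Ccn1 was higher by 1.13. Glycolysis and glucose uptake genes were higher, with 16 of 25 above 0 and a median of 0.26 at percentile 99.5, or 0.17 at percentile 99.1 with median centring and with the values as deposited. Eno3, the muscle enolase, was higher by 0.88, Pfkfb1 by 0.83, Ldhb by 0.67 and Pgam2 by 0.63. The hypoxia and angiogenesis list had a median of -0.25 at percentile 2.39, or 5.15 with the 75th percentile filter, with 11 of 16 below 0 and P4ha2 at -0.78.

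Fibroblast markers were lower, with 14 of 17 below 0 and a median of -0.25 at percentile 1.54, or 3.18 with median centring and with deposited values. Dcn, which encodes decorin, differed by -1.01, Vim by -0.98 and Cd34 by -0.63. The matrix list was not apart here and had no settled direction, with a median of -0.03, a mean of 0.07, and a median of 0.08 with no filter on dim genes and 0.01 with the mean over probes. Endothelial markers had a median of -0.19 at percentile 5.17, or 1.97 with no filter. Of the fixed markers, Myh7 differed by -0.72, Col1a1 by -0.66, Nppa by -0.57, Nppb by -0.37 and Myh6 by -0.28. Col3a1 (-0.11), Atp2a2 (-0.06), Acta1 (-0.04), Rcan1 (-0.04) and Postn (0.17) differed little.

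At 2-fold, 62 genes were higher and 76 lower in STIM1KO TAC than in WT TAC. The split was 46 and 97 with the values as deposited, and 45 and 98 with median centring. Ttc13 (2.30), Mfsd6 (1.99), Fez2 (1.93), Myot (1.74), Trim25 (1.60) and Prdx5 (1.50) were the highest. The brightest probe of Ttn, the giant sarcomere protein titin, was higher by 1.37, while the other 2 probes differed by -0.26 and -0.25. Camk2n1 was the lowest, at -3.65 with the offset before log2, again with the dim value of 2.31 on the STIM1KO TAC array that leaves its size open. It was followed by H2az1 (-1.74), Ric3 (-1.60), Babam1 (-1.59), Id3 (-1.56), Pdzd9 (-1.55) and Myom2 (-1.55), which encodes an M-band protein of the sarcomere.

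The sham and TAC genotype comparisons share no array and correlated at r = 0.32 (Spearman 0.34) across genes. No gene was at 2-fold higher in both, and 4 were at 2-fold lower in both, Adhfe1, Cacna2d1, Necap2 and Xlr3b. If every gene is equally likely to reach 2-fold, 0.40 were expected, with the same limit as for the responses. The 37 genes lower in STIM1KO sham had a median of -0.36 between the TAC arrays, and 25 of them were below 0 there.

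The last comparison took the response in STIM1KO minus that in WT. Matrix genes were above 0 in 26 of 35 cases, with a median of 0.23 at percentile 99.8, led by Col1a2 (1.36), Thbs2 (0.95), Col5a1 (0.90) and Sparc (0.84). Macrophage and monocyte markers moved the same way, with 12 of 17 above 0 and a median of 0.22 at percentile 98.1. Their median was 0.056 with median centring and 0.13 with deposited values, at a percentile of 94.6 that both share by construction. The percentile was 95.6 with no filter and 96.3 with the 75th percentile filter. Fibroblast markers had a median of -0.09 at percentile 26.7. Immediate early and heat shock genes had a median of -0.35 at percentile 0.18, with 10 of 16 below 0, or 34.1 with no filter on dim genes. Both the matrix and the macrophage values include the STIM1KO sham array, which was low in these genes against WT sham. The matrix value also includes the WT sham array, against which WT TAC was low as well, at -0.14. In the comparisons without WT sham the matrix list was not apart. It was at 0.12 and percentile 92.2 in the STIM1KO response, and at -0.03 and percentile 25.2 between the TAC arrays.

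**Figure D3:**
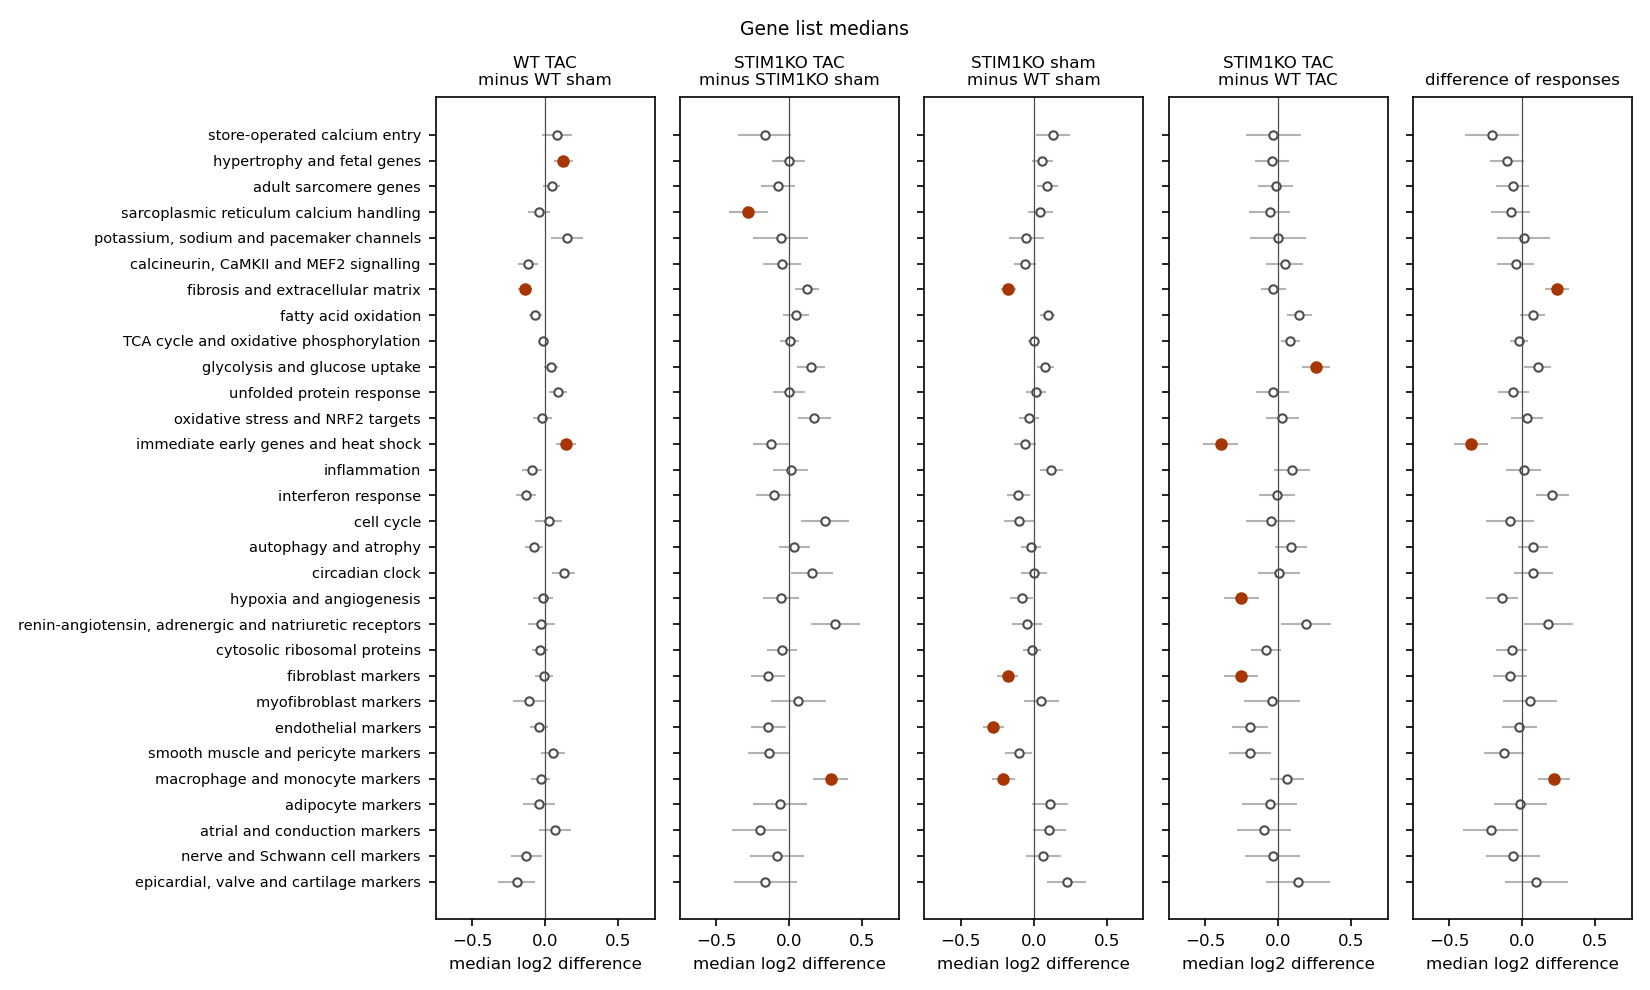
Median log2 difference (horizontal axes) of 30 gene lists in the 5 comparisons, 1 point per list, with bars of 1 SD of the medians of matched random lists and filled points for lists apart from random lists. Of the 150 medians, 16 are apart, and 4 of these lie below 0 in STIM1KO sham against WT sham. For lists of unrelated genes 7.5 would be expected, which need not hold where the genes of a list vary together. The medians are also not independent, since comparisons share arrays and some lists share genes.

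At 2-fold, 101 genes had a higher and 50 a lower response in STIM1KO, or 80 and 69 with median centring, which moved the median of all filtered genes to -0.10. Ttc13 (2.99), Mrpl2 (2.65), Vegfb (2.64), Chac1 (2.43) and St8sia4 (2.10) were the highest. Of these, Mrpl2, Vegfb, Chac1 and St8sia4 had their lowest value on the STIM1KO sham array, and Ttc13 on WT TAC. Ric3 (-1.69), Pon2 (-1.63), Myom2 (-1.58), Mybpc2 (-1.49) and Sod1 (-1.43) were the lowest after Camk2n1, whose size is open for the reason given above. Myh7 differed by -1.19 between the responses, and the hypertrophy and fetal genes as a list by a median of -0.11 at percentile 18.7, which is not apart from random lists.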

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

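The tests of technical explanations in this part were all chosen after the results were seen. The test on skeletal muscle genes was run first on the members with a value on all 4 arrays and then rewritten for the members passing the filter, after the first result was known. Both versions are given. The criterion for exchanged arrays was also tightened after its first result, to ask for all 3 scalings and for the matrix genes.

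Ttc13 and Mrpl2 were 2-fold lower after TAC in WT and 2-fold higher in STIM1KO. The normalized intensities of Ttc13 were 101 in WT sham, 26.5 in WT TAC, 62.4 in STIM1KO sham and 131 in STIM1KO TAC, and those of Mrpl2 were 1369, 525, 315 and 758 in the same order. Their differences of responses were 2.99 for Ttc13 and 2.65 for Mrpl2. With 1 array per group this difference between genotypes was not tested.

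The STIM1KO response held 130 genes at 2-fold and the WT response 22. None of the 3 scalings brought the numbers together, and the lowest ratio was 5.73. Of the 3, 2 only shift each array by a constant, which cannot change the spread of differences. The array medians also lay close, within 0.101. These scalings therefore could hardly have removed a wider spread, and the ratio does not decide on scaling in general. Error of single probes remains a candidate. For the 53 genes with 2 probes, its SD was 0.26 in the WT response and 0.28 between the sham arrays. It was 0.42 in the STIM1KO response, 0.37 between the TAC arrays and 0.39 in the difference of responses. The covariance of the 2 probes was 0.0150 in the WT response and 0.0152 in the STIM1KO response, where r was 0.0812. For these genes, the 2 probes thus differed more from each other in the STIM1KO response, while their covariance was about equal as a point estimate. The bootstrap interval of r was wide, at -0.19 to 0.48 in the WT response and -0.22 to 0.36 in the STIM1KO response. A larger shared part in the STIM1KO response is therefore not excluded, and the covariances do not decide where its wider spread lay. Between the TAC arrays and in the difference of responses the covariance was 0.039 and 0.054. There r was 0.22 and 0.26, against 0.19 in the WT response. A difference between genotypes may also contribute, but no test here separates it from a noisier STIM1KO TAC array.

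In STIM1KO sham, 37 genes were 2-fold lower and 2 higher than in WT sham. The choice among the 3 scalings is argued against, because the share lower was at least 90.0% under each. They move the arrays little, since the array medians spread over 0.101, so other forms of scaling were not tested. Low values on the STIM1KO sham array alone are argued against as the whole cause, since the same genes had a median of -0.36 between the TAC arrays, below all matched random lists. They remain a candidate explanation for part, since 9 of the 37 genes were at least 2-fold below all 3 other arrays, with Vegfb 2.36 below the lowest of them. A genotype effect for the rest is a hypothesis, and a difference in the share of cell types was not tested.

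Acta1 was lower after TAC in both genotypes, and sham and TAC arrays exchanged in both cannot be told apart from the given labels here. The heart weight to body weight averages were 4.1 and 6.7 in WT and 4.5 and 4.9 in STIM1KO. They belong to the labelled groups of animals and would be the same if RNA or arrays were exchanged afterwards, so they do not decide it. Against an exchange, the 16 other hypertrophy and fetal genes had a median of 0.13 in WT at percentile 98.6, among them Nppb at 0.58 and Myh7 at 0.59. Their percentile was 99.0 with median centring and with the values as deposited, which share it by construction. Leaving out Acta1, the lowest member, cannot lower the median. With Acta1 kept the percentile was 98.2, or 95.2 under those 2 scalings and 92.6 with the 75th percentile filter, which are not apart. Also against an exchange, matrix genes had a median of 0.12 in STIM1KO at percentile 92.2, which is not apart. As an exchange would give, matrix genes in WT had a median of -0.14 at percentile 0.38, and Myh7 in STIM1KO differed by -0.59, while the hypertrophy and fetal genes in STIM1KO, at 0.05 and percentile 64.8, decide neither way. Skeletal muscle carried over into the sham samples is argued against as the whole cause, since 11 other skeletal muscle genes had medians of -0.18 in WT and 0.32 in STIM1KO, and the 4 passing the filter -0.24 and 0.29, though Myl1 differed by -0.76 in WT. For errors of the single Acta1 probe that are independent between the 2 responses, 0.00199 genes were expected as low as Acta1 in both. The 1 gene seen is Acta1 itself, whose own values set the cutoffs, so this count cannot decide. Such errors, a probe prone to large errors on every array and a response of Acta1 to TAC all stay open.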

How the results depend on the processing

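All alternatives in this part were planned before the data were examined and all were run, although genes below a stricter filter have no value there. With 1 array per group, none of them measures variation between animals, and for the values that moved the cause was not tested beyond what each setting does by construction. Genes higher and lower at 2-fold are given as pairs, in the order WT response, STIM1KO response, STIM1KO against WT in sham, STIM1KO against WT in TAC, and difference of responses. At 1.5-fold they were 109 and 91, 513 and 499, 86 and 192, 443 and 577, and 572 and 417. At 3-fold they were 1 and 4, 13 and 1, 0 and 12, 5 and 4, and 21 and 3. Without a filter on dim genes, where more genes enter, they were 131 and 161, 488 and 328, 145 and 230, 381 and 375, and 725 and 481. With the 75th percentile filter they were 2 and 5, 38 and 14, 0 and 20, 25 and 21, and 47 and 14. With an offset before log2, which shrinks differences of dim genes, 4 genes were higher in the WT response, 27 lower in the STIM1KO response, 46 lower in STIM1KO TAC and 25 lower in the difference of responses. With median centring 4 genes were higher in STIM1KO sham. Other counts stayed within 1.5 times.

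The correlation of the 2 responses was 0.165 with no filter, and that of the 2 genotype comparisons 0.191. Of the 16 medians apart, 13 stayed apart with median centring and the same 13 with deposited values, where percentiles are equal by construction. With no filter 13 stayed apart, 11 with the 75th percentile filter, 16 with an offset and 16 with the mean over probes. In turn, medians not apart in the main setting became apart, the same 2 with median centring and with deposited values. There were 11 with no filter, 4 with the 75th percentile filter, 0 with an offset and 1 with the mean over probes. With no filter these included cell cycle genes in WT (percentile 99.4), in STIM1KO sham (0.49) and between the TAC arrays (0.21), store-operated calcium entry genes between the TAC arrays (1.28), smooth muscle markers in WT (0.14) and hypertrophy genes in the difference of responses (1.71). With the 75th percentile filter they included immediate early genes in STIM1KO (0.0) and oxidative stress genes in STIM1KO (99.5) and in the difference of responses (99.9). With no filter, hypertrophy and fetal genes in WT had a median of 0.20, matrix genes in STIM1KO sham -0.082 and immediate early genes in the difference of responses -0.042. With the 75th percentile filter, immediate early genes reversed to -0.034 in WT and were at -0.55 in STIM1KO TAC against WT TAC, matrix genes were at -0.29 and fibroblast markers at -0.33 in STIM1KO sham, and fibroblast markers at -0.41 between the TAC arrays. With median centring, glycolysis genes between the TAC arrays were at 0.17 and macrophage markers in the difference of responses at 0.056. Among named genes, Atp2a2 in the sham comparison reversed, to -0.055 with the values as deposited. In all, 1382 values of named genes kept their direction and their side of 2-fold, 16 no longer reached it and 5 newly did. Of the 1382, the 259 with no filter and the 109 with the 75th percentile filter could not change, since a filter does not alter a gene's value. Nor can the mean over probes alter a gene with 1 probe. Empty cells and the unstated background correction limit what the lowest signals show.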

Other observations

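Of the 30 lists with a percentile, 21 were apart in no comparison in the main setting, with medians from -0.22 to 0.31 and percentiles from 3.65 to 97.3. Renin-angiotensin, adrenergic and natriuretic receptor genes had a median of 0.31 in the STIM1KO response at percentile 97.3, with 6 of 8 above 0 and Rgs2, a regulator of G-protein signalling, higher by 0.91. The percentile was 98.5 with median centring and with the values as deposited, and with no filter on dim genes the median was 0.14 at percentile 81.1. Interferon response genes had a median of -0.13 in the WT response, with 13 of 17 below 0 and a percentile of 3.65. Circadian clock genes had a median of 0.13 there, with 10 of 12 above 0 and a percentile of 97.0, or 97.7 with median centring and with the values as deposited.

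Fatty acid oxidation genes had a median of -0.07 in the WT response, with 18 of 31 below 0, but its direction turned with the scaling, to 0.03 with the values as deposited. The members that differed most were Pdk4 (-1.10), which restrains pyruvate dehydrogenase, the uncoupling protein gene Ucp3 (-0.98), the coactivator Ppargc1b (-0.68) and Acsl1 (-0.58). Between the TAC arrays Pdk4 was higher in STIM1KO by 1.11 and Ppara differed by -0.96, while the fatty acid oxidation genes had a median of 0.14 at percentile 93.9, not apart from random lists, though at 98.1 with no filter and 99.4 with the mean over probes. The list of tricarboxylic acid cycle and oxidative phosphorylation genes had a median of -0.01 in the WT response over 51 genes, which was 0.04 with median centring and 0.07 with the values as deposited. In the STIM1KO response it was 0.00, or -0.03 with median centring and 0.07 with the values as deposited, although Cox6a2 differed by -0.87 in the latter.

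The lists with fewer than 5 members passing the filter were those of neutrophils, of T, NK and B cells and of erythroid cells and platelets, with 3 genes each, skeletal muscle and thymus markers with 4, and sex-linked genes with 1. In the WT response their medians were -0.08, -0.18, 0.12, -0.24 and 0.34, and in the STIM1KO response -0.14, 0.65, 0.16, 0.29 and 0.48. Among 2117 probes above the filter level without a symbol here, 11 were 2-fold higher and 2 lower in the WT response, and 22 higher and 13 lower in the STIM1KO response.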
